A study of Mus musculus with 18 samples.

How the data were processed

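Epidermal basal cells of mouse embryos were profiled at E18.5, after shRNA had been delivered to the epidermis by in utero injection at E9.5, per the labels. The 3 conditions were WT with a scrambled shRNA (WT shScram), HrasG12V with the scrambled shRNA (HrasG12V shScram) and HrasG12V with an shRNA against Eif2b5 (HrasG12V shEif2b5). Each condition had 3 libraries of ribosome footprints, made in the presence of cycloheximide, and 3 libraries of RNA, so that 18 libraries were compared. The design held no WT shEif2b5 group. Per the labels, the HrasG12V mice were of strain FR-HrasG12V and the WT mice carried a tdTomato and EGFP reporter at the Gt(ROSA)26Sor locus, so strain and genotype cannot be separated. The genotype label of WT shScram footprint replicate 1 reads Rosa26 where the other WT labels read WT, and that library was kept with the WT group.

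Per the labels, the authors used Bowtie, TopHat2 and HTSeq with the mm10 genome, and no version or strand setting is stated. The deposited table holds raw read counts over coding sequences per gene symbol, which the authors did not normalise further. All of its per-sample columns were used. Symbols were matched to the GENCODE mouse annotation of mm10 through current names and synonyms, and 98.7% found a gene (19771 by symbol and 607 by synonym). The table held 27 date-like names left by spreadsheet software, which were kept as written, and no mitochondrially encoded gene. The columns were checked for copies, and libraries of 1 group differed from each other with a chi-square of 3.35 to 21.1 per degree of freedom.

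Gene-level tests used edgeR 4.0.16 in R 4.3.3. Genes passed filterByExpr (minimum count 10, minimum total 15), library sizes were scaled by TMM within each library kind, and a quasi-likelihood model with robust dispersion was fitted to the 9 libraries of a kind. The term translation efficiency is used here for the interaction of condition and library kind in 1 model over all 18 libraries, which tests whether the footprint difference departs from the RNA difference. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within 1 comparison, and adjusted p-values of genes are from this edgeR test unless another tool is named. Values are in CPM (counts scaled to library size) after TMM scaling, given as mean ± SD (n = 3 libraries per group), and fold changes are given with the model's standard error (SE) on the log2 scale. The p-values measure only the spread between these libraries, since no label says that the 3 libraries of a group came from separate animals or litters. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so single genes were judged by the model fitted across genes.

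Before the data were examined, 38 gene lists were fixed. They covered cell types of skin (basal keratinocyte, spinous keratinocyte, granular and cornified layer, hair follicle, wound and stress keratinocyte, melanocyte, Merkel cell, dermal fibroblast, immune, endothelial, erythroid, skeletal muscle, Y-linked), signalling and cell state (RAS-ERK output, immediate early and dissociation, Notch targets, Wnt targets, interferon response, p53 targets, cell fate transcription factors, SCF F-box proteins, S phase, G2/M phase, replication-dependent histones), translation and stress (eIF2B and eIF2 subunits, other initiation factors, ATF4 targets, uORF-controlled mRNAs that respond to eIF2, ER chaperones with the unfolded protein response, cytosolic tRNA synthetases, cytosolic ribosomal proteins, other TOP mRNAs) and metabolism (mitochondrial ribosomal proteins, nuclear OXPHOS subunits, mitochondrially encoded proteins, proteasome subunits, cholesterol synthesis, glycolysis). Lists with at least 3 tested members were compared with all other tested genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, on signed square roots of the F statistics, with p-values adjusted over lists and the 3 comparisons of a kind. The preset correlation was compared with an estimated one and with the fry rotation test, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. For each list, the members past an adjustment over the list alone were also counted.

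The genes named in the text followed a rule fixed at the same time. Hras, Eif2b5 and Fbxo32 were named in every comparison. The 8 highest and the 8 lowest fold changes were taken among called genes with at least 10 CPM in the higher group and no overlap between the groups, leaving out predicted gene models. From each list, up to 4 called members with the smallest p were taken, or up to 2 without a call, given as values. Genes named outside the rule are marked as chosen after their values were seen.

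Alternatives changed 1 choice at a time. They were DESeq2 1.42.0 median-of-ratios factors or upper-quartile factors in place of TMM, no filter, a filter at a mean of 10 CPM, the 20 most abundant genes left out, the DESeq2 Wald test, limma-voom with quality weights, only the 2 conditions compared in the fit, the replicate number as a block (for translation efficiency also nested in condition), separate fits for translation efficiency, and each library left out in turn. After the data were examined, a further pair was added, namely offsets that remove each library's smooth trend with coding GC and coding length (mgcv 1.9.3, basis size 6, genes above a log2 CPM of 3) and leaving out HrasG12V shScram RNA libraries 1 and 3 together. No label says that a replicate number marks a shared animal, litter or day, and the fits gave libraries of the same number no common term outside the block alternative.

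The pipeline was tested on simulated data, in which the counts of 200 genes were changed. At a 2-fold change it recovered 78%, 68% and 76% of genes in RNA for HrasG12V shScram against WT shScram, HrasG12V shEif2b5 against HrasG12V shScram and HrasG12V shEif2b5 against WT shScram, 68%, 76% and 60% in footprints and 38%, 44% and 34% in translation efficiency. At 1.5-fold it recovered 18%, 12% and 14% in RNA, 36%, 44% and 22% in footprints and 4%, 6% and 8% in translation efficiency. Most changes of 1.5-fold were thus not detected at this depth, spread and number of libraries. Intervals for ratios of small counts are exact Clopper-Pearson intervals at a level of 0.95 and cover counting error only, since no label mentions molecular identifiers. Figures were drawn with matplotlib 3.10.9.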

Results

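Ribosome footprints and RNA were sequenced from enriched epidermal basal cells of mouse embryos at E18.5, in 3 conditions with 3 libraries of each kind (18 libraries). HrasG12V encodes an oncogenic form of the small GTPase that feeds the RAS-ERK pathway, and Eif2b5 encodes the catalytic subunit of eIF2B, the exchange factor that keeps initiation factor eIF2 active. RNA coding-sequence counts ran from 1771365 (HrasG12V shScram library 2) to 5505386 (WT shScram library 3). HrasG12V shScram libraries 1 and 3 held 5214473 and 4310239, and the 3 HrasG12V shEif2b5 libraries 2758443, 2812627 and 2209327. WT shScram libraries 1 and 2 held 2523896 and 2707252. Footprint totals were 4933298, 4793575 and 4835210 for HrasG12V shEif2b5, 4579407, 3641185 and 4502203 for HrasG12V shScram, and 3319175, 4294388 and 3853760 for WT shScram. After filtering, 11096 genes were tested in RNA, 11448 in footprints and 10793 for translation efficiency, with biological coefficients of variation of 0.162, 0.14 and 0.149.

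The targeted gene, Eif2b5 (ENSMUSG00000003235.13; mm10 chromosome 16, 20498817 to 20509323, plus strand), had RNA levels of 158, 179 and 159 CPM in the WT shScram libraries, 127, 388 and 145 CPM in HrasG12V shScram and 134, 128 and 143 CPM in HrasG12V shEif2b5. Its footprints stood at 102, 106 and 102 CPM, 91.9, 93.1 and 102 CPM, and 82.7, 78.5 and 95.4 CPM. Against HrasG12V shScram, the shEif2b5 libraries differed by a log2 fold change of −0.68 in RNA (95% interval −1.52 to 0.17, adjusted p 0.257) and −0.16 in footprints (−0.41 to 0.08, adjusted p 0.994). Against WT shScram the footprint difference was −0.27 (−0.52 to −0.02), with an unadjusted p of 0.0331 and an adjusted p of 0.299, and the RNA difference was −0.29 (−1.13 to 0.55, adjusted p 0.927). A knockdown to 50% or less in footprints lies outside both footprint intervals, while the RNA interval against HrasG12V shScram includes it. None of these tests passed, and 1 library (HrasG12V shScram RNA 2, at 388 CPM) set both the spread and the difference in RNA. Without it the RNA difference from HrasG12V shScram was −0.00 (adjusted p 0.993).

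Hras (ENSMUSG00000025499.18; chromosome 7, 141189105 to 141194005, minus strand) had RNA levels of 232 ± 25.7, 211 ± 27.5 and 270 ± 44.7 CPM (SD, n = 3 each) in WT shScram, HrasG12V shScram and HrasG12V shEif2b5. The adjusted p was 0.623 for HrasG12V shScram against WT shScram, 0.14 for HrasG12V shEif2b5 against HrasG12V shScram and 0.836 for HrasG12V shEif2b5 against WT shScram. Hras footprints stood at 76.6 ± 9.01, 78.6 ± 3.53 and 85.2 ± 21.2 CPM (adjusted p 0.95, 0.994 and 0.705 in the same order). Counts per gene carry no allele, so they do not show the G12V change itself. Fbxo32 (ENSMUSG00000022358.7; chromosome 15, 58175879 to 58214932, minus strand), an F-box ubiquitin ligase gene, was at 9.52 ± 1.11, 7.26 ± 1.36 and 8.96 ± 2.44 CPM in RNA and 15.4 ± 5.17, 18.8 ± 2.46 and 14.4 ± 4.43 CPM in footprints, and passed no test. Its footprint difference between HrasG12V shEif2b5 and HrasG12V shScram was −0.39 (adjusted p 0.994).

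**Figure D1:**
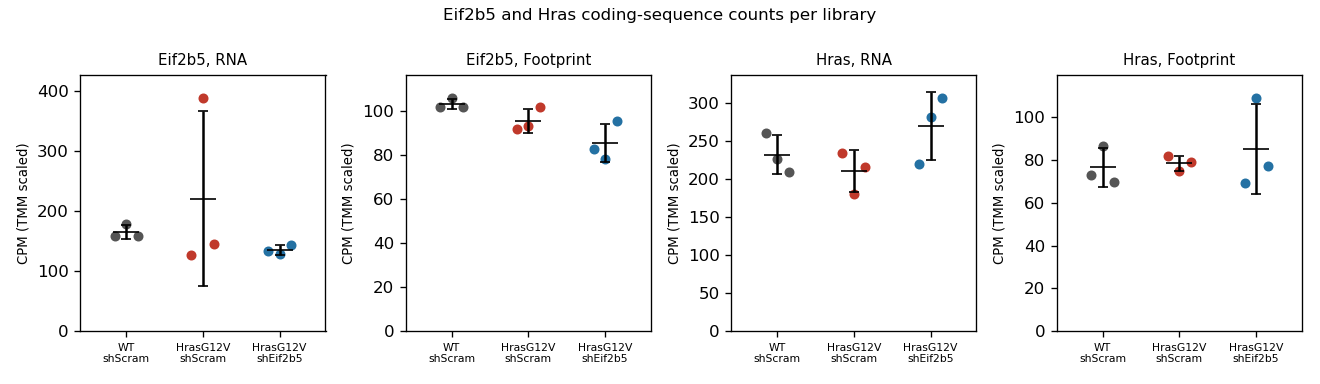
Eif2b5 and Hras in each RNA and footprint library, in CPM (y axis) by condition (x axis), with points for libraries and bars for mean ± SD. HrasG12V shScram RNA library 2 stands at 388 CPM for Eif2b5, above the 127 and 145 CPM of the other 2 libraries of its group.

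The first comparison asked what oncogenic Hras did to translation and RNA in these cells, with HrasG12V shScram set against WT shScram. In footprints, genes that ERK signalling induces or uses as feedback rose. Dusp6, which encodes an ERK phosphatase, rose 2.83-fold (SE 0.12 on the log2 scale, n = 3 each, 340 ± 49.6 against 120 ± 6.01 CPM, adjusted p 1.48e-06). Etv4 and Etv5, ETS transcription factors downstream of ERK, rose 3.68-fold (log2 1.88, SE 0.17, adjusted p 3.35e-06) and 2.57-fold (log2 1.36, SE 0.15, adjusted p 3.49e-05). Spry4, a feedback inhibitor of the pathway, rose 6.15-fold (11.5 ± 1.27 against 1.9 ± 1.26 CPM, adjusted p 0.000676), and Junb rose 1.92-fold (adjusted p 0.00203). The cytokine genes Tslp and Ccl20 were near absent in WT shScram. Ccl20 rose by 4.21 on the log2 scale (SE 0.37, 12.9 ± 0.755 against 0.671 ± 0.291 CPM, adjusted p 3.14e-06). Tslp had 235 footprint counts in HrasG12V shScram against 1 in WT shScram, a ratio of 223 (39.7 to 8.86e+03; adjusted p 1.3e-06). The Wnt inhibitor gene Wif1 (3.32-fold, adjusted p 1.3e-05), the cell surface gene Thy1 (3.25-fold, adjusted p 1.97e-05) and Ehd3 (6.44-fold, adjusted p 0.000184) rose as well. Foxi3, a hair placode regulator, fell by 0.94 on the log2 scale (SE 0.15, 59.7 ± 4.43 against 114 ± 19.4 CPM, adjusted p 0.00259). The cystatin gene Stfa3, whose reads its near-identical neighbours share and whose level is therefore uncertain, rose 1.69-fold (adjusted p 0.00291). These 12 genes were called in each of the 6 fits without 1 library and in every alternative that tested them. Tslp, Ccl20, Ehd3 and Spry4 were not tested with the filter at a mean of 10 CPM, nor Stfa3 with the 20 most abundant genes left out.

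In all, edgeR called 195 footprint genes between these groups (141 higher and 54 lower, 63 of them by more than 2-fold), against 1632 at an unadjusted p under 0.05. Of all tested genes, 20.3% separated the 3 libraries of one group from the 3 of the other, against the 10% that chance gives. All 195 called genes did, but a call from the same libraries favours this, so it is no separate support. The DESeq2 and voom alternatives called 260 and 316. Among the 8 highest by rule were also S100a9 (8.6-fold, adjusted p 0.0202), Prr9 (8.65-fold, adjusted p 0.0365), Fabp4 (log2 2.51, adjusted p 0.0164) and the EGFR ligand gene Epgn (4.05-fold, adjusted p 0.0164). The 8 lowest were Steap3 (−1.55, adjusted p 0.0104), Adamts19 (−1.33), Col8a1 (−1.30, adjusted p 0.0104), Sprr1a (−1.23, adjusted p 0.021), Fmo1 (−1.07), Atp6v1b1 (−1.06), Tgfbi (−1.05, 79.3 ± 13 against 164 ± 20.9 CPM, adjusted p 0.0185) and Pdlim4 (−1.02, adjusted p 0.0071). Each of these 12 lost its call in at least 1 fit without a library. The highest adjusted p there was 0.112 for S100a9, 0.106 for Fabp4 and 0.146 for Adamts19 (each without WT shScram library 2), 0.0749 for Col8a1 (WT shScram library 2) and 0.103 for Tgfbi (WT shScram library 1). It was 0.156 for Prr9 and Sprr1a, 0.0903 for Epgn, 0.157 for Fmo1 and 0.11 for Atp6v1b1 (without HrasG12V shScram library 1) and 0.0633 for Steap3 and 0.0606 for Pdlim4 (without HrasG12V shScram library 3). The count itself was 73, 96 and 79 without HrasG12V shScram library 1, 2 or 3, and 106, 83 and 559 without WT shScram library 1, 2 or 3.

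Among the fixed lists in footprints, the RAS-ERK output list was higher with the smallest camera p (9 of 22 called, all higher, 9 higher and 1 lower adjusted over the list alone, median log2 fold change 0.74; camera adjusted p 1.61e-22). It was the only list of this comparison to pass with an estimated correlation (adjusted p 0.016). The wound and stress keratinocyte list was higher (3 of 17 called, 6 adjusted over the list alone, median 0.50, adjusted p 7.48e-10; adjusted p = 0.433 with an estimated correlation). The hair follicle list was lower (3 lower and 1 higher of 18, 7 lower and 1 higher adjusted over the list alone, median −0.23, adjusted p 6.64e-05; adjusted p = 0.119 with an estimated correlation). Its called members were Foxi3, Shh (−0.57, SE 0.14, adjusted p 0.0469), the Hedgehog receptor gene Ptch1 (−0.54, adjusted p 0.04) and Krt17 (0.66, adjusted p 0.0303). Without a single library their adjusted p reached 0.232 for Shh and 0.2 for Ptch1 (HrasG12V shScram library 2) and 0.159 for Krt17 (WT shScram library 2). Merkel cell genes were lower (0 of 7 called, 4 adjusted over the list alone, median −0.76, adjusted p 0.00337; adjusted p = 0.431 with an estimated correlation), and the list's adjusted p was 0.053 without HrasG12V shScram library 2 and 0.0522 without WT shScram library 3. Merkel marker sums were 35.5, 24.9 and 40.6 CPM in HrasG12V shScram footprints and 49.1, 56.9 and 60.6 CPM in WT shScram. Replication-dependent histones, whose reads several copies share, were lower (3 of 56, 11 lower and 1 higher adjusted over the list alone, median −0.21, adjusted p 0.00109; adjusted p = 0.647 with an estimated correlation).

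Translation and metabolism lists also stood higher in the same footprints. Cytosolic ribosomal proteins stood higher (2 of 77 called, 4 adjusted over the list alone, median 0.14, adjusted p 6.73e-06; adjusted p = 0.548 with an estimated correlation). So did other TOP mRNAs (0 of 18, 2 adjusted over the list alone, median 0.18, adjusted p 0.00296) and other initiation factors (1 of 28, 4 adjusted over the list alone, median 0.15, adjusted p 0.00339), both with adjusted p = 0.431 with an estimated correlation. The same direction was seen for cholesterol synthesis (0 of 23, 5 adjusted over the list alone, median 0.29, adjusted p 3.97e-06), glycolysis (0 of 17, 6 adjusted over the list alone, median 0.14, adjusted p 0.000328) and nuclear OXPHOS subunits (1 of 75, 4 adjusted over the list alone, median 0.12, adjusted p 0.00337). Those 3 had adjusted p = 0.431, 0.586 and 0.431 with an estimated correlation. With offsets for coding GC and length, the adjusted p was 0.0899 for ribosomal proteins and 0.568 for OXPHOS. ATF4 targets were higher (2 of 30 called, 5 adjusted over the list alone, median 0.14, adjusted p 0.0125; adjusted p = 0.647 with an estimated correlation), with Psat1 (721 ± 19.1 against 491 ± 78.6 CPM, adjusted p 0.0272) and Slc7a1 (1.47-fold, adjusted p 0.0342) past the test. The list's adjusted p was 0.369 without WT shScram library 1 and 0.223 without library 3, and that of Psat1 reached 0.124 without HrasG12V shScram library 1 and that of Slc7a1 0.214 without library 3. Atf4 itself, whose mRNA carries upstream reading frames read through when eIF2 is limiting, rose 2.13-fold in footprints (47.7 ± 5.18 against 22.3 ± 9.14 CPM, adjusted p 0.0272, and 0.139 without HrasG12V shScram library 1). Its RNA difference was 0.35 (adjusted p 0.135) and the test of its translation efficiency gave 0.74 (adjusted p 0.167). ER chaperones were higher (0 of 20 called, 0 adjusted over the list alone, median 0.14, adjusted p 0.0124; adjusted p = 0.431 with an estimated correlation). This was lost without HrasG12V shScram library 1 (0.0573) or WT shScram library 3 (0.116).

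**Figure D2:**
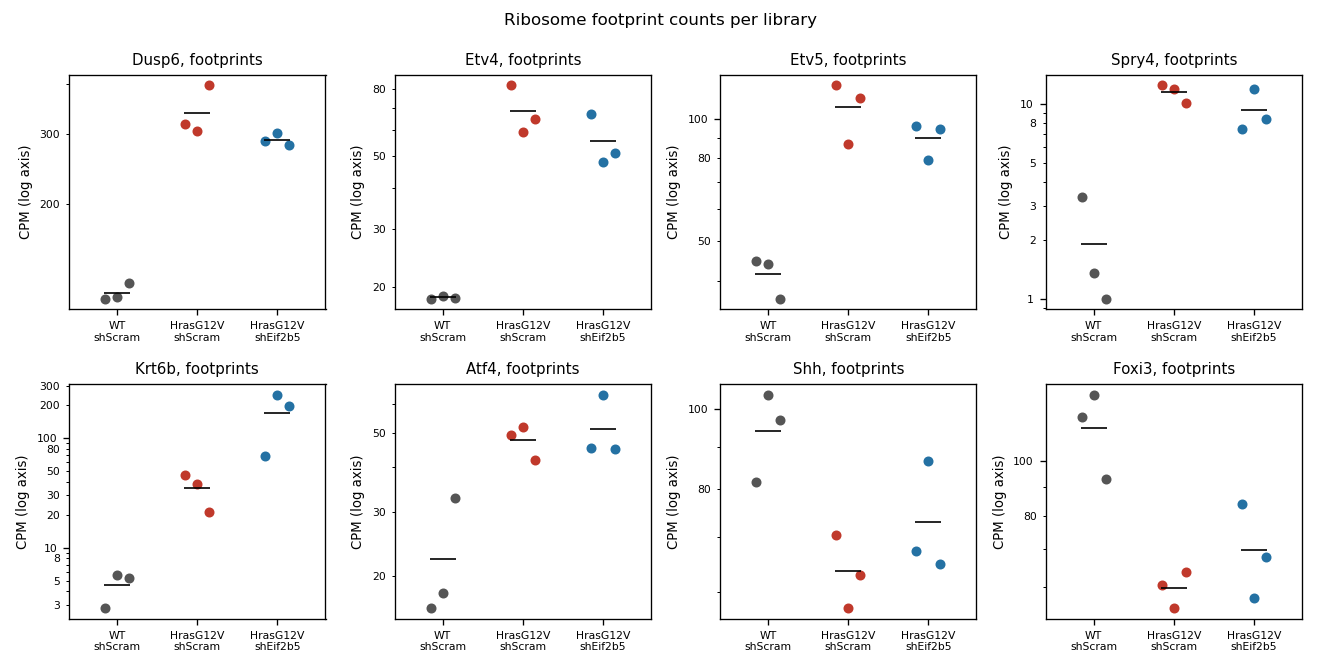
Footprint CPM per library (y axis, log scale) by condition (x axis) for 8 genes, with a bar at each group mean. Dusp6 averages 120, 340 and 291 CPM in WT shScram, HrasG12V shScram and HrasG12V shEif2b5, and Krt6b 4.57, 35.1 and 170 CPM.

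In RNA, the same comparison again placed the ERK output genes high. Etv4 rose 3.26-fold (log2 1.71, SE 0.16, n = 3 each, 93.6 ± 13.8 against 28.9 ± 2.19 CPM, adjusted p 7.56e-05), Dusp6 2.6-fold (adjusted p 0.000332) and Spry1 2.48-fold (adjusted p 0.000576). The stress keratin gene Krt6b rose 7.09-fold (36.8 ± 14.2 against 5.11 ± 1.09 CPM, adjusted p 0.000147), although Krt6a shares most of its sequence and the split of reads between them is uncertain. Aldh1a3, a retinoic acid synthesis gene, rose 26.2-fold (10.7 ± 1.58 against 0.385 ± 0.0217 CPM, adjusted p 0.000103), Wif1 6.1-fold (adjusted p 0.000332), Prr9 4.77-fold (adjusted p 0.000576) and the immediate early gene Egr1 2.09-fold (adjusted p 0.00602). Tslp had 96 counts against 1, a ratio of 87 (15.2 to 3.47e+03; adjusted p 0.000332). Stfa2 and Stfa3 rose 4.23-fold and 2.79-fold (adjusted p 0.000736 and 0.00051, uncertain because of shared reads), and the OXPHOS gene Ndufa4 rose 2.6-fold (52.6 ± 1.35 against 20.2 ± 2.82 CPM, adjusted p 0.000576). These 12 genes kept their calls in every alternative that tested them (Aldh1a3 and Tslp were not tested with the filter at a mean of 10 CPM), including the fit without HrasG12V shScram RNA libraries 1 and 3.

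All 9 RNA libraries together gave 854 genes (516 higher and 338 lower, 245 by more than 2-fold; 2809 at an unadjusted p under 0.05), of which 829 (97.1%) separated the groups, against 26.1% of all tested genes and the 10% that chance gives. Without HrasG12V shScram libraries 1 and 3 together the count was 47 (43 higher and 4 lower), with the lone library of that group assumed to vary like the other groups. It was 246, 2431 and 294 without HrasG12V shScram library 1, 2 or 3, and 189, 218 and 397 without WT shScram library 1, 2 or 3. Offsets for coding GC and length gave 409 (269 higher and 140 lower), voom 1724, and a fit of these 2 conditions alone 389. Gsta4 (6.25-fold, adjusted p 0.00286), Ehd3 (6.2-fold, adjusted p 0.000576), Spry4 (6.83-fold, adjusted p 0.000983) and Lipk (log2 2.31, adjusted p 0.00286) completed the 8 highest, and had adjusted p of 0.074, 0.0519, 0.0718 and 0.17 without both libraries. The 8 lowest were Adamts19 (−1.87, adjusted p 0.0038), Pet117 (−1.81), Skint9 (−1.76), Ankrd55 (−1.68), the Wnt target Sp5 (−1.58, SE 0.28, adjusted p 0.00446), Fgfbp3 (−1.53), Slc39a2 (−1.37) and Adgrb2 (−1.36). Without both libraries their adjusted p was 0.0718, 0.342, 0.215, 0.478, 0.349, 0.512, 0.193 and 0.172, in that order. With 1 library left out, it reached 0.0798 for Skint9 and 0.062 for Ankrd55 (HrasG12V shScram library 3), 0.0797 for Fgfbp3 (WT shScram library 1) and 0.0632 for Slc39a2 (WT shScram library 2).

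Lists higher in RNA for HrasG12V shScram against WT shScram began with wound and stress keratinocyte (8 of 14 called, all higher, 11 adjusted over the list alone, median 1.17, adjusted p 1.53e-18; adjusted p = 0.221 with an estimated correlation and 0.00901 by fry) and RAS-ERK output (6 of 18 higher, 7 higher and 1 lower adjusted over the list alone, median 0.53, adjusted p 5.65e-08; adjusted p = 0.21 with an estimated correlation). Metabolic lists were also higher, namely cholesterol synthesis (11 of 23 higher, 14 adjusted over the list alone, median 0.52, adjusted p 3.59e-07) and nuclear OXPHOS subunits (12 higher and 2 lower of 75, 21 and 2 adjusted over the list alone, median 0.29, adjusted p 5e-06). They had adjusted p = 0.598 and 0.21 with an estimated correlation. The others were melanocyte (2 of 11 higher, 8 adjusted over the list alone, median 0.69, adjusted p 9.21e-05), proteasome subunits (7 of 36 higher, 7 adjusted over the list alone, median 0.25, adjusted p 0.00586) and mitochondrial ribosomal proteins (3 of 77 higher, 0 adjusted over the list alone, median 0.17, adjusted p 0.0393). These had adjusted p = 0.598, 0.626 and 0.21 with an estimated correlation. Lower were hair follicle (4 of 18, 9 adjusted over the list alone, median −0.42, adjusted p 0.000115), basal keratinocyte (1 of 15, 5 adjusted over the list alone, median −0.27, adjusted p 0.0337) and Wnt targets (4 lower and 1 higher of 13, 8 and 1 adjusted over the list alone, median −0.52, adjusted p 0.0337), with adjusted p = 0.626, 0.866 and 0.626 with an estimated correlation. Members included Shh (−1.05, SE 0.20, 80.9 ± 22.2 against 165 ± 3.39 CPM, adjusted p 0.00734), the basal keratin gene Krt15 (−0.98, adjusted p 0.004), Tyr (1.09, adjusted p 0.00514), Cox7a2 (1.06, adjusted p 0.000983), Psma3 (0.98, adjusted p 0.00698) and Idi1 (1.28, adjusted p 0.00351). Without HrasG12V shScram libraries 1 and 3, the adjusted p was 0.309 for Shh, 0.17 for Krt15, 0.124 for Tyr, 0.0747 for Cox7a2, 0.49 for Psma3 and 0.283 for Idi1. The list p-values there were 0.00154 for OXPHOS, 0.00604 for cholesterol synthesis, 0.235 for hair follicle, 0.373 for the proteasome, 0.178 for mitochondrial ribosomal proteins, 0.0724 for basal keratinocyte and 0.725 for Wnt targets. With the GC and length offsets, basal keratinocyte (0.45), mitochondrial ribosomal proteins (0.388), proteasome (0.321) and Wnt targets (0.141) were past no threshold. Basal keratinocyte was also lost without HrasG12V shScram library 1 (0.183) or 2 (0.0727) or WT shScram library 3 (0.306). Mitochondrial ribosomal proteins were lost without HrasG12V shScram library 1 (0.0649) or 2 (0.0798) or WT shScram library 3 (0.0687). Wnt targets were lost without HrasG12V shScram library 1 (0.123) or 3 (0.0676) or WT shScram library 1 (0.0525).

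Translation efficiency for HrasG12V shScram against WT shScram asked whether footprints moved apart from RNA. Fxyd3, a regulator of the sodium pump, was lower by 1.81 on the log2 scale (SE 0.25, n = 3 each, adjusted p 0.000711), and this call held in every alternative and in all 12 fits without 1 library. Ndufa4 (−1.58, SE 0.29, adjusted p 0.0119), Cox7a2 (−1.08, adjusted p 0.0119), Tmem33 (−1.85, adjusted p 0.00937) and Hist1h3a (−1.65, adjusted p 0.00937, uncertain because histone copies share reads) held in all 12 fits. Ndufa4 footprints stood at 220 ± 18.9 against 254 ± 95.4 CPM while its RNA rose. Without HrasG12V shScram RNA libraries 1 and 3 the adjusted p of these 4 was 0.174, 0.172, 0.242 and 0.153, and that of Fxyd3 0.0192. In all, 126 genes were called (16 higher and 110 lower, 1705 at an unadjusted p under 0.05), of which 109 were also called in RNA and 9 in footprints. In 112 of them the RNA difference was the larger, with a median size of 0.90 against 0.24 in footprints. The other lowest genes were Hist1h4j (−2.20), Sprr1a (−1.88), Tbp (−1.76), Cfap20 (−1.74), Nutf2 (−1.68) and Lage3 (−1.68). The highest were Pet117 (2.11, adjusted p 0.0271), Ctnnbip1 (1.40), Fbxo9 (1.26), Pdzd4 (1.26), Banf1 (1.17), Mif4gd (1.17), Id1 (1.15) and Klhl18 (1.14). None of these 14 kept its call in all 12 fits, with a highest adjusted p of 0.071 for Hist1h4j (without HrasG12V shScram footprint library 3) to 0.135 for Sprr1a, Lage3 and Banf1 (without WT shScram footprint library 1). The melanocyte list (median −0.50, 1 of 11 lower, 1 adjusted over the list alone, adjusted p 0.00233) and the histones (median −0.26, 4 of 56 lower, 8 adjusted over the list alone, adjusted p 0.00366) were lower, both with adjusted p = 0.796 with an estimated correlation. The count was 26, 21 and 13 without HrasG12V shScram footprint library 1, 2 or 3, and 11, 70 and 381 without WT shScram footprint library 1, 2 or 3. For RNA libraries it was 14, 693 and 20 without HrasG12V shScram RNA library 1, 2 or 3, and 29, 32 and 59 without WT shScram RNA library 1, 2 or 3. It was 8 without HrasG12V shScram RNA libraries 1 and 3 (2 higher and 6 lower), 267 by DESeq2, 432 by voom, 430 with separate fits and 43 with these 2 conditions alone.

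The second comparison asked what the shRNA against Eif2b5 did in HrasG12V cells, with HrasG12V shEif2b5 set against HrasG12V shScram. In footprints, no gene passed the edgeR test (0 called, 519 at an unadjusted p under 0.05), while DESeq2 called 1 and voom 3. Fn1, which encodes fibronectin, came closest (log2 0.88, SE 0.14, n = 3 each, 864 ± 170 against 471 ± 52.7 CPM, adjusted p 0.0931) and was the DESeq2 call (adjusted p 0.000104). The voom calls were Fn1 (adjusted p 0.0103), Ccl20 (−1.47, adjusted p 0.0462) and Krt81 (3.74, adjusted p 0.0462). Fn1, Ccl20 and Krt81 were chosen after their values were seen. Without HrasG12V shEif2b5 footprint library 1 the test called 31 genes (30 higher and 1 lower), among them, as chosen after their values were seen, the keratins Krt6a (log2 2.55), Krt6b (2.66) and Krt16 (2.17), the desmosome gene Dsp (1.29) and Plec (1.26). That library held spinous marker sums of 2.96e+04 CPM, against 8.26e+04 and 8.18e+04 CPM in the other 2 libraries of its group and 4.61e+04, 4.05e+04 and 3.95e+04 CPM in HrasG12V shScram. Without HrasG12V shEif2b5 library 3 it called 1 (lower), and without any other single library 0. With all libraries, Krt6b footprints stood at 170 ± 91.4 against 35.1 ± 12.7 CPM (adjusted p 0.994), Atf5 at 12 ± 2.27 against 7.96 ± 1.81 CPM (adjusted p 0.994) and Tslp at 8.95 ± 1.86 against 19.2 ± 7.28 CPM (adjusted p 0.994).

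No fixed list had a member past the test over all genes between these footprints (0 called by edgeR in all, 519 at an unadjusted p under 0.05, 1 by DESeq2 and 3 by voom). Cytosolic tRNA synthetases, whose genes ATF4 induces, stood higher (18 of 20 members positive, 0 adjusted over the list alone, median 0.18, adjusted p 8.46e-06; adjusted p = 0.447 with an estimated correlation). ER chaperones stood lower (17 of 20 negative, 0 adjusted over the list alone, median −0.15, adjusted p 7.83e-05; adjusted p = 0.431 with an estimated correlation), and both of these held in each fit without 1 library. Immune genes stood lower (12 of 14 negative, 0 adjusted over the list alone, median −0.51, adjusted p 0.000284; adjusted p = 0.431 with an estimated correlation), with marker sums of 58.5, 66.7 and 56.5 CPM against 95.6, 67.7 and 88.5 CPM. Histones (42 of 56 positive, median 0.19, adjusted p 7.83e-05) and G2/M genes (22 of 26 positive, median 0.13, adjusted p 0.000234) stood higher, with adjusted p = 0.447 and 0.572 with an estimated correlation, and both were lost without HrasG12V shEif2b5 library 1 (0.153 and 0.683). ATF4 targets were higher (21 of 30 positive, 0 adjusted over the list alone, median 0.15, adjusted p 0.0275; adjusted p = 0.708 with an estimated correlation), but not without HrasG12V shEif2b5 library 2 (0.0569) or 3 (0.151) or HrasG12V shScram library 3 (0.0973). RAS-ERK output was lower (14 of 22 negative, 1 adjusted over the list alone, median −0.09, adjusted p 0.0187; adjusted p = 0.431 with an estimated correlation). This was lost without HrasG12V shEif2b5 library 1 (0.0825) or HrasG12V shScram library 3 (0.0679). Basal keratinocyte genes were higher (13 of 15 positive, median 0.09, adjusted p 0.00694; adjusted p = 0.647 with an estimated correlation). This was lost without HrasG12V shEif2b5 library 1 (0.16) or 2 (0.0648), without HrasG12V shScram library 1 (0.207), or with GC offsets (0.904). The wound and stress list was higher (13 of 17 positive, 2 higher and 1 lower adjusted over the list alone, median 0.21, adjusted p 0.0232; adjusted p = 0.792 with an estimated correlation). This was lost without HrasG12V shEif2b5 library 2 (0.37) or 3 (0.216) or HrasG12V shScram library 3 (0.531). Dermal fibroblast genes were lower (median −0.67, adjusted p 0.0228; adjusted p = 0.773 with an estimated correlation). This was lost without HrasG12V shEif2b5 library 1 (0.274) or 2 (0.185) or HrasG12V shScram library 3 (0.615), which held 3.64e+03 CPM of their markers against 2.65e+03 and 2.67e+03 in the other 2. OXPHOS genes were lower (49 of 75 negative, median −0.05, adjusted p 0.0327; adjusted p = 0.506 with an estimated correlation). This was lost without HrasG12V shEif2b5 library 1 (0.226) or 2 (0.254) or HrasG12V shScram library 1 (0.299) or 2 (0.097), or with GC offsets (0.568). The list of uORF-controlled mRNAs had a median of 0.04 (adjusted p 0.401).

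In RNA, HrasG12V shEif2b5 against HrasG12V shScram differed in both directions among stress keratinocyte genes. Krt6b rose 3.76-fold (log2 1.91, SE 0.23, n = 3 each, 137 ± 9.04 against 36.8 ± 14.2 CPM, adjusted p 0.000512) and Krt16 2.41-fold (385 ± 58.9 against 160 ± 39.3 CPM, adjusted p 0.00187). The wound and stress list as a whole was not past the test (3 higher and 5 lower of 14 called, 3 and 9 adjusted over the list alone, median −0.62, adjusted p 0.147; adjusted p = 0.866 with an estimated correlation). Stfa3 (−1.69, SE 0.19, 889 ± 176 against 2880 ± 609 CPM, adjusted p 0.000229), the lysosomal membrane gene Lamp2 (−1.69, SE 0.19, 43.1 ± 6.02 against 138 ± 36.1 CPM, adjusted p 0.000229) and Ndufa4 (−1.64, SE 0.19, 16.7 ± 3.32 against 52.6 ± 1.35 CPM, adjusted p 0.000339) fell. These 5 genes kept their calls in every alternative, with Krt6b and Stfa3 uncertain because of shared reads. Their footprint differences were not past the test. Stfa3 footprints stood at 7270 ± 769 against 8880 ± 1090 CPM and Ndufa4 footprints at 212 ± 16.3 against 220 ± 18.9 CPM. Krt6b footprints stood at 68.8, 246 and 196 against 45.9, 38.2 and 21.1 CPM and Krt16 at 102, 560 and 546 against 133, 134 and 103 CPM. Shh rose 2.03-fold (162 ± 44.4 against 80.9 ± 22.2 CPM, adjusted p 0.00736), with 0.0505 without HrasG12V shEif2b5 library 3 and no call without HrasG12V shScram 1 and 3. Its footprints were 67.4, 86.5 and 65 against 70.5, 57.4 and 63 CPM. Of 29 ATF4 targets (list adjusted p 0.236), only Trib3 was called. It rose 1.98-fold (24 ± 0.692 against 12.3 ± 2.22 CPM, adjusted p 0.0175), up to 0.0797 without HrasG12V shScram library 3 and uncalled without 1 and 3.

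The RNA count was 1444 genes (580 higher and 864 lower, 73 and 269 by more than 2-fold; 3387 at an unadjusted p under 0.05), and 1316 of them (91.1%) separated the groups, against 28.6% of all tested genes and the 10% that chance gives. Without HrasG12V shScram RNA libraries 1 and 3 it was 17 (3 higher and 14 lower), with the same assumption for the lone library. It was 404, 3150 and 445 without HrasG12V shScram library 1, 2 or 3, and 480, 1006 and 197 without HrasG12V shEif2b5 library 1, 2 or 3. GC and length offsets gave 613 (291 higher and 322 lower), voom 2248 and a fit of these 2 conditions alone 876. The other highest genes were Pet117 (1.91, adjusted p 0.00417), Adamts19 (1.69), the pyrimidine enzyme gene Tymp (1.59), Tusc1 (1.55), Rassf8 (1.52), Krt6a (1.48, adjusted p 0.00633) and Csf2ra (1.47). The other lowest were Orm1 (−2.06), Gpr160 (−1.97), Zfp81 (−1.76), Tspan6 (−1.74), Gtf2a2 (−1.70) and Zfp729b (−1.68). None of these 13 was called without HrasG12V shScram libraries 1 and 3 (adjusted p 0.0904 for Tymp to 0.716 for Tusc1). With 1 library left out, calls were lost for Krt6a (0.0505), Tymp (0.0575) and Tusc1 (0.216) at the most without HrasG12V shEif2b5 library 3, for Orm1 (0.0835) without HrasG12V shEif2b5 library 1 and for Zfp729b (0.0584) without HrasG12V shScram library 3.

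By list, RNA of nuclear OXPHOS subunits was lower (18 lower and 3 higher of 75, 27 and 6 adjusted over the list alone, median −0.31, adjusted p 3.65e-05), as was that of cholesterol synthesis (9 of 23, 10 lower and 1 higher adjusted over the list alone, median −0.45, adjusted p 4.94e-05) and the proteasome (11 lower and 1 higher of 36, 16 and 2 adjusted over the list alone, median −0.30, adjusted p 0.000154). Those lists had adjusted p = 0.21, 0.626 and 0.626 with an estimated correlation. The hair follicle list (6 higher and 1 lower of 18, 11 and 1 adjusted over the list alone, median 0.50, adjusted p 0.000222) and Wnt targets (3 higher and 1 lower of 13, 5 and 1 adjusted over the list alone, median 0.29, adjusted p 0.0393) were higher, with adjusted p = 0.626 and 0.678 with an estimated correlation. The members Cox7a2 (−1.03, adjusted p 0.00258), Sc5d (−1.46, adjusted p 0.00272), Idi1 (−1.21, adjusted p 0.00447), Psma2 (−1.14, adjusted p 0.00272), Psma3 (−1.26, adjusted p 0.00272) and, of lists not past the test (adjusted p 0.153 and 0.748), Serpinb5 (−0.94, adjusted p 0.00313) and Hist1h4c (−1.01, adjusted p 0.00291) held in all 6 fits without 1 library. Without HrasG12V shScram libraries 1 and 3 their adjusted p was 0.143, 0.138, 0.366, 0.16, 0.282, 0.145 and 0.208, in that order. The lists there had 0.000796 for OXPHOS, 0.0228 for cholesterol synthesis and for the proteasome, 0.166 for hair follicle and 0.716 for Wnt targets. The hair follicle list had an adjusted p of 0.141 and Wnt targets 0.331 with GC offsets, and Wnt targets were lost without HrasG12V shEif2b5 library 3 (0.0562) or HrasG12V shScram library 1 (0.105) or 3 (0.0666). The basal keratins Krt14 (0.66, adjusted p 0.029) and Krt5 (0.61, adjusted p 0.042) rose, with adjusted p up to 0.116 and 0.16 without HrasG12V shScram library 1. The basal list was not past the test (2 of 15 called, 9 positive and 6 negative, adjusted p 0.108). HrasG12V shScram RNA held basal marker sums of 1.17e+04, 1.55e+04 and 1.39e+04 CPM, against 1.99e+04, 1.77e+04 and 1.84e+04 CPM in HrasG12V shEif2b5 and 1.78e+04, 1.68e+04 and 2.19e+04 CPM in WT shScram.

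HrasG12V shScram RNA libraries 1 and 3 stood apart from the other 7 RNA libraries. On the first principal component (37.9% of variance) they lay at 40.8 and 40.3, and the others between −26.8 and 1.32. Their levels correlated with coding GC across genes (−0.44 and −0.584, others −0.0873 to 0.475). HrasG12V shEif2b5 libraries had the opposite sign (0.316, 0.118 and 0.475). The 10% of genes lowest in coding GC stood 0.68 and 0.90 (log2) above the highest 10%, against −0.58 to 0.09 in the others. Footprint libraries had −0.28 to 0.24.

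**Figure D3:**
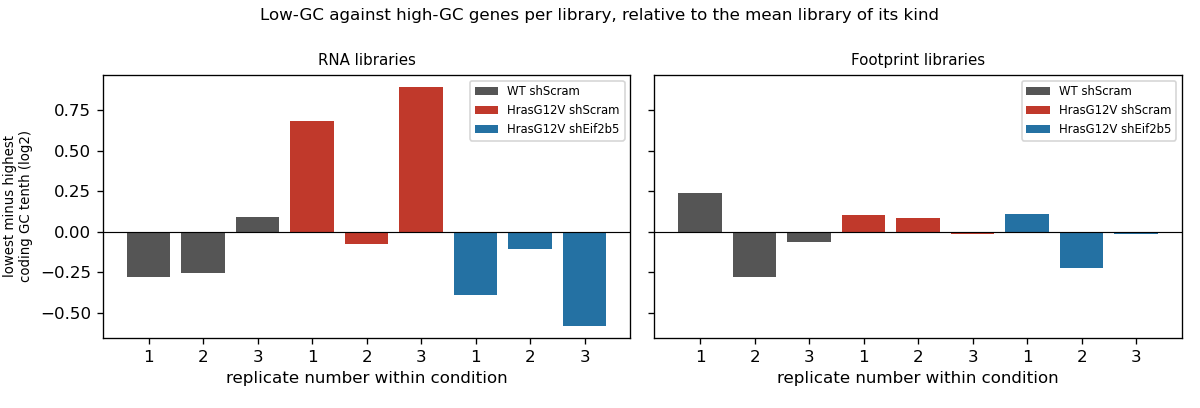
Level of the 10% of genes with the lowest coding GC minus the 10% with the highest (y axis, log2) for each RNA and footprint library (x axis). HrasG12V shScram RNA libraries 1 and 3 stand at 0.68 and 0.90.

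These RNA differences were mostly absent from footprints. Of the 569 genes higher in RNA and tested in footprints, 367 (64.5%) had a footprint difference of the same sign, with medians of 0.69 in RNA and 0.06 in footprints. Among the 864 lower, 598 (69.2%) had the same sign, with medians of −0.84 and −0.07. For HrasG12V shScram against WT shScram the medians were 0.86 and 0.13 for 513 higher genes and −0.72 and −0.22 for 328 lower genes, and 78 genes were called in both kinds, all in the same direction (6.32 higher and 1.61 lower for independent lists). Across the 10793 genes tested in both, which are not independent replicates, fold changes of the 2 kinds correlated at r = 0.359 for HrasG12V shScram against WT shScram, 0.221 for HrasG12V shEif2b5 against HrasG12V shScram and 0.428 for HrasG12V shEif2b5 against WT shScram.

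**Figure D4:**
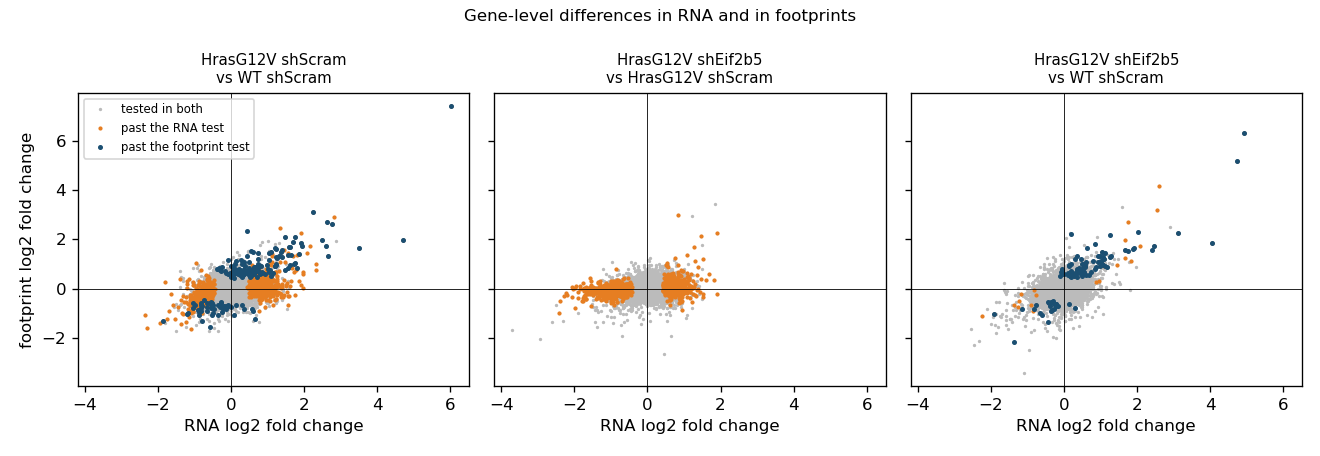
Footprint log2 fold change (y axis) against RNA log2 fold change (x axis) for genes tested in both kinds (grey), with genes past the RNA test in orange and past the footprint test in blue, in 3 panels for the 3 comparisons. In the middle panel the orange genes spread along the RNA axis, with medians of 0.69 and −0.84 in RNA and 0.06 and −0.07 in footprints.

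Translation efficiency between HrasG12V shEif2b5 and HrasG12V shScram mirrored the RNA calls. Stfa3 was higher (1.40, SE 0.24, n = 3 each, adjusted p 0.0102; RNA −1.69 and footprints −0.29), and this call held in all 12 fits without 1 library but not without HrasG12V shScram RNA libraries 1 and 3 (0.237). Ndufa4 (1.58, adjusted p 0.0137; RNA −1.64 and footprints −0.06), Psma2 (1.03, adjusted p 0.0178; RNA −1.14 and footprints −0.10) and Sc5d (1.30, adjusted p 0.024; RNA −1.46 and footprints −0.15) were higher. In all, 228 genes were called (194 higher and 34 lower, 2061 at an unadjusted p under 0.05), of which 218 were called in RNA and 0 in footprints, and in 222 the RNA difference was the larger (median size 1.03 against 0.10). The highest were Hist1h4j (2.03), Tspan6 (1.78), Cfap20 (1.70), Ormdl2 (1.69), Lage3 (1.68), Immp1l (1.66), Nup35 (1.64) and Ndrg3 (1.64). The lowest were Pet117 (−2.13), Rpl41 (−1.63), Ttc19 (−1.48), Tacc1 (−1.33), Bok (−1.29), Fadd (−1.24), Pawr (−1.22) and Pdf (−1.14). None of these 16 kept its call in all 12 fits or without HrasG12V shScram RNA libraries 1 and 3. Without HrasG12V shEif2b5 RNA library 3 the adjusted p was 0.064 for Ndufa4 and Bok, 0.0756 for Psma2, 0.102 for Sc5d, 0.0616 for Ndrg3 and 0.137 for Pawr. The called lists had adjusted p = 0.796 with an estimated correlation, except spinous (0.825). Those that stood higher were wound and stress (1 of 14, 1 adjusted over the list alone, median 0.72, adjusted p 0.00316), proteasome (5 of 36, 9 adjusted over the list alone, median 0.27, adjusted p 0.00134). Also higher were cholesterol synthesis (2 of 23, 8 adjusted over the list alone, median 0.30, adjusted p 0.00188), OXPHOS (7 of 75, 16 higher and 2 lower adjusted over the list alone, median 0.30, adjusted p 0.00931) and spinous keratinocyte (1 of 16, 3 adjusted over the list alone, median 0.52, adjusted p 0.0477). Hair follicle was lower (0 of 18, 1 higher and 2 lower adjusted over the list alone, median −0.40, adjusted p 0.00366). Spinous keratinocyte was lost without HrasG12V shEif2b5 footprint library 2 (0.288) or 3 (0.118), HrasG12V shEif2b5 RNA library 2 (0.0654) or 3 (0.0579), HrasG12V shScram footprint library 3 (0.103) or RNA library 1 (0.184) or 2 (0.0967). It was also lost with the 20 most abundant genes left out (0.0737), the filter at a mean of 10 CPM (0.0851) and separate fits (0.0676). Without HrasG12V shScram RNA libraries 1 and 3 the adjusted p was 0.0581 for the proteasome, 0.154 for cholesterol, 0.0705 for OXPHOS and 0.563 for hair follicle, and GC offsets gave 0.355 for hair follicle. The count was 203, 188 and 25 without HrasG12V shEif2b5 footprint library 1, 2 or 3, and 64, 53 and 34 without HrasG12V shScram footprint library 1, 2 or 3. Among RNA libraries it was 48, 254 and 7 without HrasG12V shEif2b5 RNA library 1, 2 or 3, and 63, 1350 and 26 without HrasG12V shScram RNA library 1, 2 or 3. It was 2 without HrasG12V shScram RNA libraries 1 and 3, 111 with GC offsets (82 higher and 29 lower), 445 by DESeq2, 636 by voom and 731 with separate fits.

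The third comparison asked how far HrasG12V cells with the Eif2b5 shRNA stood from WT shScram. In footprints the ERK output genes again stood high. Dusp6 rose 2.42-fold (log2 1.28, SE 0.12, n = 3 each, 291 ± 10.9 against 120 ± 6.01 CPM, adjusted p 2.66e-05), Etv4 2.98-fold (adjusted p 4.88e-05), Etv5 2.17-fold (adjusted p 0.000611) and Spry4 4.96-fold (adjusted p 0.00282). Tslp had 124 counts against 1, a ratio of 107 (18.8 to 4.24e+03; adjusted p 2.66e-05). The glutathione transferase gene Gsta4 (3.13-fold, adjusted p 2.66e-05), Wif1 (3.28-fold, adjusted p 2.66e-05), Thy1 (2.69-fold, adjusted p 0.000244), Ehd3 (4.8-fold, adjusted p 0.00182) and Junb (2-fold, adjusted p 0.00174) rose. The chemokine receptor gene Cxcr4 fell by 1.06 on the log2 scale (SE 0.12, 49.3 ± 2.99 against 103 ± 5.06 CPM, adjusted p 0.000117), Bbox1 by 1.01 (adjusted p 0.00265) and the simple epithelial keratin gene Krt7 by 0.98 (adjusted p 0.00566). These 13 genes kept their calls in every fit without 1 library and every alternative that tested them (Tslp, Ehd3 and Spry4 were not tested with the filter at a mean of 10 CPM). Krt6b rose 36.3-fold (log2 5.18, SE 0.69, 170 ± 91.4 against 4.57 ± 1.56 CPM, adjusted p 0.0333), with an adjusted p of up to 0.153 (without WT shScram library 1).

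Altogether 111 footprint genes were called (87 higher and 24 lower, 41 by more than 2-fold; 1648 at an unadjusted p under 0.05), and all 111 separated the groups, against 16.1% of all tested genes and the 10% that chance gives. The split was 63 higher and 31 lower with upper-quartile factors (67% higher, against 78.4%). DESeq2 called 229, the fit without a filter 216 and the fit of these 2 conditions alone 44. S100a9 (9.94-fold, adjusted p 0.0214), Pla2g4e (log2 2.18, adjusted p 0.0147) and Ifi202b (1.65, adjusted p 0.0201, with near-identical relatives) were among the highest, and Col8a1 (−1.34, adjusted p 0.0131), Tmem256 (−0.91, adjusted p 0.047), Mme (−0.85), Alad (−0.82, adjusted p 0.01) and Arg2 (−0.81, adjusted p 0.0138) among the lowest. Without 1 library their adjusted p reached 0.0888 for S100a9 and 0.0836 for Ifi202b (WT shScram library 2), 0.11 for Pla2g4e and 0.183 for Mme (WT shScram library 1), and 0.0795 for Col8a1, 0.169 for Tmem256, 0.0641 for Alad and 0.0887 for Arg2 (HrasG12V shEif2b5 library 3). The count was 316, 37 and 44 without HrasG12V shEif2b5 library 1, 2 or 3 and 49, 49 and 407 without WT shScram library 1, 2 or 3.

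RAS-ERK output led the footprint lists against WT shScram (7 of 22 higher, 10 adjusted over the list alone, median 0.74, adjusted p 4.82e-16; 0.017 with an estimated correlation), followed by wound and stress keratinocyte (3 of 17, 9 adjusted over the list alone, median 0.70, adjusted p 4.82e-16; adjusted p = 0.431 with an estimated correlation). Genes tied to translation and amino acids also stood higher. They were cytosolic tRNA synthetases (0 of 20, 6 adjusted over the list alone, median 0.28, adjusted p 2.57e-06) and cytosolic ribosomal proteins (3 of 77, 11 higher and 1 lower adjusted over the list alone, median 0.16, adjusted p 6.74e-07). Both lost their call with an estimated correlation (0.433 and 0.548). With them stood ATF4 targets (2 of 30, 7 adjusted over the list alone, median 0.24, adjusted p 2.01e-05), other TOP mRNAs (0 of 18, 6 adjusted over the list alone, median 0.18, adjusted p 6.64e-05) and other initiation factors (0 of 28, 4 higher and 1 lower adjusted over the list alone, median 0.19, adjusted p 0.000213). These 3 had adjusted p = 0.433, 0.431 and 0.431 with an estimated correlation. Atf4 rose 2.29-fold (51.3 ± 10.7 against 22.3 ± 9.14 CPM, adjusted p 0.0257; up to 0.101 without WT shScram library 1), Atf5 2.17-fold (12 ± 2.27 against 5.49 ± 0.185 CPM, adjusted p 0.047; up to 0.163 without HrasG12V shEif2b5 library 2) and Psat1 1.45-fold (adjusted p 0.0494; up to 0.238 without HrasG12V shEif2b5 library 3). Both Atf4 and Atf5 belong to the list of uORF-controlled mRNAs, which stood higher by camera (2 of 12, 4 adjusted over the list alone; adjusted p 0.0426; adjusted p = 0.431 with an estimated correlation) with a median of 0.04 and 6 members of each sign. That list was lost without HrasG12V shEif2b5 library 1 (0.0508) or 2 (0.143) or WT shScram library 1 (0.0686) or 2 (0.135).

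Of the remaining footprint lists against WT shScram, cholesterol synthesis (0 of 23, median 0.28, adjusted p 0.000213), glycolysis (0 of 17, 4 adjusted over the list alone, median 0.18, adjusted p 0.00116) and spinous keratinocyte (0 of 16, median 0.33, adjusted p 0.0125) were higher. They had adjusted p = 0.431, 0.647 and 0.773 with an estimated correlation. Hair follicle (1 lower and 1 higher of 18, 2 and 1 adjusted over the list alone, median −0.24, adjusted p 0.00225), immune (0 of 14, median −0.49, adjusted p 0.0125) and Merkel cell (0 of 7, 1 adjusted over the list alone, median −0.43, adjusted p 0.03) were lower. The values with an estimated correlation were 0.431, 0.506 and 0.431. Foxi3 (−0.72, adjusted p 0.0283) and Krt17 (0.81, adjusted p 0.0137) were the called hair follicle genes, with adjusted p up to 0.138 and 0.0702 without HrasG12V shEif2b5 library 2. Spinous keratinocyte was lost without HrasG12V shEif2b5 library 2 (0.384) or 3 (0.0587), without WT shScram library 1 (0.0656) or 3 (0.504), and with the 20 most abundant genes left out (0.0956). Glycolysis was lost without WT shScram library 3 (0.052), immune without WT shScram library 1 (0.0686) and Merkel cell without HrasG12V shEif2b5 library 1 (0.125) or WT shScram library 3 (0.19). Merkel marker sums were 29.6, 41.5 and 47.2 CPM against 49.1, 56.9 and 60.6 CPM in WT shScram.

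In RNA, stress keratins rose between WT shScram and HrasG12V shEif2b5. Krt6b rose 26.7-fold (log2 4.74, SE 0.29, n = 3 each, 137 ± 9.04 against 5.11 ± 1.09 CPM, adjusted p 1.06e-07), Krt16 6.06-fold (385 ± 58.9 against 64 ± 11 CPM, adjusted p 8.13e-07) and Krt6a 5.9-fold (47.3 ± 20.7 against 8.13 ± 2.07 CPM, adjusted p 0.000621). Etv4 rose 3.2-fold (adjusted p 3.74e-05), Dusp6 2.42-fold (adjusted p 0.00079), Ehd3 8.7-fold (adjusted p 0.000152), Fgd5 4.23-fold (adjusted p 0.000289) and Wif1 5.53-fold (adjusted p 0.000787). These 8 genes kept their calls in every alternative and every fit without 1 library. Tslp had 31 counts against 1, a ratio of 42.8 (7.14 to 1.75e+03; adjusted p 0.00951, up to 0.0912 without WT shScram library 3). Adh1 (−1.22; 51 against 119 CPM, adjusted p 0.0089, up to 0.0783 without HrasG12V shEif2b5 library 2), the Wnt receptor gene Ror1 (−1.24, adjusted p 0.0089, up to 0.0763 without HrasG12V shEif2b5 library 3) and the gap junction gene Gjb5 (−1.16, adjusted p 0.0263, up to 0.214 without WT shScram library 2) fell.

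RNA calls against WT shScram numbered 36 (25 higher and 11 lower, 27 by more than 2-fold; 812 at an unadjusted p under 0.05), and all 36 separated the groups, against 16% of all tested genes and the 10% that chance gives. DESeq2 called 64, voom 136, the fit without a filter 72, the fit of these 2 conditions alone 123 and the fit without HrasG12V shScram RNA libraries 1 and 3, which are not in this comparison but share its spread, 124. The count was 14, 13 and 12 without HrasG12V shEif2b5 library 1, 2 or 3 and 20, 13 and 18 without WT shScram library 1, 2 or 3. Of the 36, 16 were also called in footprints in the same direction (0.192 higher and 0.0245 lower for independent lists), and the 25 higher genes had medians of 1.66 in RNA and 1.28 in footprints. Spry2 (2.05-fold, adjusted p 0.00861) and Spry1 (2.04-fold, adjusted p 0.0133) rose, with adjusted p up to 0.0763 without HrasG12V shEif2b5 library 3 and 0.0954 without WT shScram library 3. Among lists, RAS-ERK output (4 of 18, 8 adjusted over the list alone, median 0.82, adjusted p 9.41e-20; 0.0308 with an estimated correlation) and wound and stress (4 of 14, 8 higher and 1 lower adjusted over the list alone, median 0.51, adjusted p 3e-23; adjusted p = 0.308 with an estimated correlation) led. ATF4 targets (0 of 29, 1 adjusted over the list alone, median 0.20, adjusted p 0.000284), cytosolic ribosomal proteins (0 of 77, median 0.12, adjusted p 0.00193), G2/M (0 of 26, median 0.18, adjusted p 0.0108) and melanocyte (0 of 11, median 0.29, adjusted p 0.0337) were higher and spinous keratinocyte lower (0 of 16, 2 adjusted over the list alone, median −0.28, adjusted p 0.000115). In that order, these had adjusted p = 0.626, 0.866, 0.832, 0.678 and 0.678 with an estimated correlation. ATF4 targets were lost without WT shScram library 3 (0.0687). Ribosomal proteins were lost without HrasG12V shEif2b5 library 3 (0.162) or WT shScram library 2 (0.07) or 3 (0.0687), and G2/M without HrasG12V shEif2b5 library 1 (0.144) or WT shScram library 1 (0.274). Melanocyte was lost without HrasG12V shEif2b5 library 1 (0.309) or WT shScram library 1 (0.198) or 2 (0.122) or HrasG12V shScram libraries 1 and 3 (0.0536), and spinous without WT shScram library 2 (0.132).

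Translation efficiency between HrasG12V shEif2b5 and WT shScram held no called gene by edgeR or by any other tool run (0 called, 634 at an unadjusted p under 0.05, smallest adjusted p 0.709), and 18 without HrasG12V shEif2b5 footprint library 1. By list, spinous keratinocyte (5 adjusted over the list alone, median 0.65, adjusted p 1.42e-07), cytosolic tRNA synthetases (median 0.24, adjusted p 0.00064), glycolysis (0.31, adjusted p 0.00138), the granular and cornified layer (0.48, adjusted p 0.0193) and cholesterol synthesis (0.19, adjusted p 0.0317) stood higher and hair follicle lower (−0.19, adjusted p 0.0101). All 6 had adjusted p = 0.796 with an estimated correlation. Spinous footprint sums were 2.96e+04, 8.26e+04 and 8.18e+04 CPM in HrasG12V shEif2b5 against 3.41e+04, 5.26e+04 and 2.84e+04 CPM in WT shScram. Granular sums were 3.03e+03, 6.62e+03 and 6.29e+03 against 3.18e+03, 6.09e+03 and 2.88e+03 CPM. HrasG12V shEif2b5 library 1 lay within the WT range on both. The granular list was lost in 6 and cholesterol in 5 of the 12 fits without 1 library, and hair follicle without HrasG12V shEif2b5 footprint library 3 (0.0712), HrasG12V shEif2b5 RNA library 1 (0.0666) or WT shScram RNA library 2 (0.063). GC offsets ended the hair follicle call (0.0818), and leaving out HrasG12V shScram RNA libraries 1 and 3 the granular call (0.0581). Atf4 differed by 0.71 (adjusted p 0.814).

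Both HrasG12V groups shared much of their footprint difference from WT shScram. Dusp6, Etv4, Etv5, Spry4, Tslp, Thy1, Wif1, Ehd3 and Junb rose and Foxi3 and Col8a1 fell in both. In total 84 genes were called in both in the same direction (65 higher and 19 lower), against 1.07 and 0.113 for independent lists and a mean of 0.2 when unchanged groups with a shared control were simulated. The fold changes correlated at r = 0.729 across genes (0.503 simulated), with a covariance of 0.109 (0.0357 simulated). The 3 WT shScram libraries cannot be split into parts of at least 2, so the part of the excess that comes from them was not measured. In RNA, 28 genes were called in both (22 higher and 6 lower; 1.16 and 0.335 for independent lists; r = 0.264, simulated 0.486; covariance 0.0409, simulated 0.0352). Of the RNA calls, 515 differed in opposite directions in the first and second comparison (350 higher and then lower, 165 lower and then higher; 40.2 and 17.7 for independent lists; 0.4 simulated), and these comparisons share the HrasG12V shScram libraries, of which 1 and 3 left out lowered their counts to 47 and 17 (r = 0.75, simulated 0.489; covariance 0.169, simulated 0.0356).

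Some fixed lists passed in no comparison in which they were tested. The eIF2B and eIF2 subunits (8 tested) had camera adjusted p of 0.367, 0.386 and 0.947 in RNA and 0.097, 0.765 and 0.15 in footprints, in the order of the comparisons. Eif2s1 RNA rose by 0.71 for HrasG12V shScram against WT shScram (adjusted p 0.0148) and was lower by 0.69 for HrasG12V shEif2b5 against HrasG12V shScram (adjusted p 0.0137), with 0.297 and 0.37 without HrasG12V shScram RNA libraries 1 and 3. For HrasG12V shEif2b5 against HrasG12V shScram footprints, the adjusted p was 0.0984 for S phase, 0.491 for SCF F-box proteins, 0.471 for interferon response, 0.198 for p53 targets, and 0.173 for Notch targets. It was 0.383 for cell fate transcription factors, 0.498 for immediate early and dissociation, 0.206 for Y-linked genes, 0.586 for skeletal muscle and 0.0864 for endothelial genes. For HrasG12V shScram against WT shScram footprints the values were 0.875, 0.864, 0.904, 0.633, 0.097, 0.657, 0.352, 0.734, 0.869 and 0.761 in the same order. Erythroid genes had 1 tested member and mitochondrially encoded genes 0, so neither list was tested. Endothelial and skeletal muscle genes had 2 and 1 in RNA and for translation efficiency, and were tested in footprints alone.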

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

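The GC and length offsets and the fit without HrasG12V shScram RNA libraries 1 and 3 were chosen after seeing the data. No named gene or list turned its direction while called. The share of higher genes among the calls did move. Without HrasG12V shScram RNA library 2 it went from 60.4% to 49.9% and 40.2% to 50.1% in RNA, and from 12.7% to 35.6% and 85.1% to 56.1% for translation efficiency, in the first 2 comparisons. For HrasG12V shEif2b5 against WT shScram it fell from 78.4% to 60.2% in footprints without WT shScram library 3 and from 69.4% to 50.4% in RNA with only the 2 conditions. Where a count moved by more than 1.5 times, the cause was not tested. DESeq2 called 1 and 229 footprint genes in the last 2 comparisons, 64 genes in RNA in the last, and 267 and 445 for translation efficiency in the first 2. In the order of the comparisons, voom called 1724, 2248 and 136 in RNA. It called 316 and 3 in footprints and 432 and 636 for translation efficiency in the first 2. Without a filter, edgeR called 1 and 216 footprint genes in the last 2 comparisons, and 72 genes in RNA in the last. With only the 2 conditions in the fit, RNA gave 389, 876 and 123, footprints 44 in the last, and translation efficiency 43 in the first. Separate fits gave 430 and 731 for translation efficiency. With GC and length offsets, RNA gave 409 and 613 and translation efficiency 111 for HrasG12V shEif2b5 against HrasG12V shScram. Without HrasG12V shScram RNA libraries 1 and 3, RNA gave 47, 17 and 124, and translation efficiency 8 and 2, with the lone library assumed to vary like the other groups. Of the lists called by camera (22 in RNA, 38 in footprints and 14 for translation efficiency), an estimated correlation left 1, 2 and 0, and fry called 12, 3 and 0.

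Leaving out 1 library, where an arm of 2 remained, the count of genes ran from 189 to 2431, 197 to 3150 and 12 to 20 in RNA, from 73 to 559, 0 to 31 and 37 to 407 in footprints, and from 11 to 693, 7 to 1350 and 0 to 18 for translation efficiency. The called lists ran from 21 to 26 in RNA, 34 to 44 in footprints and 11 to 25 for translation efficiency. Over these fits, values of named genes stayed on their side of the threshold in 1322 cases in RNA, 1256 in footprints and 2565 for translation efficiency, lost a call in 402, 187 and 397, and gained one in 16, 33 and 50. At 1.5-fold the simulated test recovered 12% to 18% of genes in RNA and 22% to 44% in footprints, with this depth, spread and number of libraries together.

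With the replicate number as a block, footprints gave 1 gene (Fn1) and 184 in the last 2 comparisons, and translation efficiency 101 for HrasG12V shEif2b5 against HrasG12V shScram. The other counts with the block were 648, 1226 and 31 in RNA, 219 in footprints and 88 for translation efficiency. Nested in condition, the block gave 164, 330 and 0 genes for translation efficiency (0 called by edgeR), and 10 lists gained a call. Within each condition, RNA and footprint libraries of the same number correlated (r of 0.15, 0.28 and 0.26 in WT shScram, 0.18, 0.054 and 0.17 in HrasG12V shScram and 0.12, 0.016 and 0.073 in HrasG12V shEif2b5, highest other number 0.0023, 0.0076 and 0.037, the last above the 0.016 of library 2). All 3 values passed 0.1 in WT shScram alone. There it is a hint of pairing from the data, not the design. Across conditions, RNA of WT shScram and HrasG12V shScram had −0.035, 0.24 and 0.29 (highest other 0.058), and RNA of WT shScram and HrasG12V shEif2b5 −0.18, 0.0043 and −0.3.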

Other observations

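The tests in this part of the genes called between HrasG12V shEif2b5 and HrasG12V shScram RNA (offsets, single libraries, footprint size) were chosen only after the result was seen. The other tests were written first. Some values belong to single libraries. WT shScram RNA library 1 held endothelial marker sums of 30.4 CPM, against 10.9 and 7.41 CPM in the other 2 WT shScram RNA libraries, and dermal fibroblast sums of 2.98e+03 CPM against 1.64e+03 and 1.04e+03 CPM. Its footprint library of the same number held 30.4 CPM of endothelial markers, against 19 and 17.8 CPM. HrasG12V shScram library 3 held 25.7 CPM of endothelial markers in RNA (19.5 and 18.3 in the others) and 27.1 in footprints (22.5 and 20.5).

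The 1444 genes called between HrasG12V shEif2b5 and HrasG12V shScram RNA were weighed against coding GC, against the HrasG12V shScram libraries and against a change in mRNA level. With GC and length offsets 613 genes were called, and 448 of the 1444 were called in the same direction (median size 0.862 to 0.771, SE 0.191 to 0.178), which argues against that trend as the whole cause. The other 996 fell to 0.569 of their size (0.74 to 0.421, SE 0.196 to 0.173). These 996 were chosen because their calls ended with the offsets, so some shrinkage of the fold was built into the set. Their fold shrank by more than the SE did. For them the trend therefore cannot be told apart from a smaller change. Over all 1444 the median size fell from 0.773 to 0.523 (0.676 of its size), which was 2.997 times the median SE of these genes. The bound of 3 times the median SE had been set for the 996 alone, and they fell short of it. With 1 HrasG12V shScram RNA library kept, assumed to vary like the other groups, the count was 2287, 17 and 2338 for libraries 1, 2 and 3. It was 1517 and 1805 with libraries 1 and 3 thinned to 1770062 and 1772336 counts. With 1 HrasG12V shEif2b5 library kept, edgeR called 0 for each (2076, 1040 and 2164 at an unadjusted p under 0.05, no other tool run), in fits whose spread holds the HrasG12V shScram libraries. HrasG12V shScram library 2 thus differed from libraries 1 and 3, and which of them stand for the condition stays open. The median footprint difference in the direction of the call was 0.0656, which argues against an mRNA change that ribosomes follow at constant efficiency. A change in mRNA with opposite translation stays open, and the shRNA and library preparation were not separated by the design.

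Eif2b5 in HrasG12V shScram RNA library 2 stood at 388 CPM, 2.7 times the median of the other 8 RNA libraries (144 CPM), rank 9 of 9191 genes. The other 4 eIF2B subunit genes had a median ratio of 1.01, which argues against a rise of the whole complex. The 13 genes within 500 kb had 0.952 and 1017 genes of similar coding GC 0.969, which argues against reads of neighbours and against a GC excess. Footprints of the same condition and number stood at 93.1 CPM, between 91.9 and 102 CPM. A gain of reads from a construct, a wrong label or a biological difference of that sample stays open and was not tested.

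The 84 footprint genes called in both HrasG12V groups against WT shScram were set against strain variants. Within 10 Mb of Hras lay 1 of the 84 (Ifitm3, against 94 of 11393 tested genes, Fisher exact p 0.503) and within 10 Mb of Gt(ROSA)26Sor 1 (Bhlhe40, against 85, exact p 0.468). This argues against variants acting on nearby genes as the whole cause. A response to HrasG12V is a hypothesis, and strain differences elsewhere in the genome or acting on distant genes stay open.

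Splits of 6 libraries into 3 against 3 number 10, too few for a share under 0.05. In RNA the real split gave 854, 1444 and 36 genes and the highest other 137, 0 and 0, with 1 split as large in each. In footprints it gave 195, 0 and 111 and the highest other 0, 1 and 138, with 1, 10 and 2 splits as large. The split of 138 genes set HrasG12V shEif2b5 library 1 with WT shScram libraries 1 and 3 against the rest, and points to a structure of the samples other than condition. Footprint sums of spinous markers (2.96e+04, 3.41e+04 and 2.84e+04 CPM against 8.26e+04, 8.18e+04 and 5.26e+04) and granular markers (3.03e+03, 3.18e+03 and 2.88e+03 against 6.62e+03, 6.29e+03 and 6.09e+03) sorted with that split. For translation efficiency the real split gave 126, 228 and 0 genes and the highest other 38, 0 and 0, with 1, 1 and 10 splits as large (0 called by edgeR, 634 at an unadjusted p under 0.05, 0 by the other tools).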
